A study of Dicentrarchus labrax with 41 samples.

How the data were processed

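The data were the scanner files of 41 arrays and the series' value table. Per the labels, total RNA of each gonad sample was extracted individually, samples with a mean RNA integrity number of at least 8.4 were kept, and Cy3-labelled cRNA was made from 100 ng of RNA, so that replicates of a group are separate gonad samples. Grouping followed the labels' age and sex: 110 dpf gonad (n = 11), 250 dpf gonad (n = 12), 350 dpf testis (n = 9) and 350 dpf ovary (n = 9). The label protocols count males and females at 110 dpf and 10 testes and 10 ovaries at 350 dpf, which differs from the labels of the individual samples, and the latter were used. Root-mean-square log2 distances between arrays of a group were at least 0.353, so no sample was counted as a duplicate of another.

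Per the file headers, the intensity of each spot was extracted with Agilent Feature Extraction 10.7.3.1 in 1 channel. The processed intensity used here was background-subtracted and detrended by that software, per the file headers, and was not normalized between arrays. The authors' deposited value table holds log2 values, 1 column for each of the 41 arrays and 1 entry for each of 20977 targets; how they were normalized between arrays is not given in the sources used here. Each of the 41 arrays correlated best with its own column after targets were centred, with r between 0.562 and 0.925, although for 6 columns another array correlated better still. The column medians lay between 8.68 and 8.95. The log2 scale and the absence of centring per target follow from these values, whereas the treatment of multiple probes and the correction between arrays stay unknown. Across targets, the mean over the slides with 350 dpf arrays minus the mean over the other slides had an SD of 0.145 in the authors' table and 1.38 in quantile-normalized scanner values, so the table holds little of the difference between the slide sets.

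Each array held 45220 spots, of which 1417 control spots were left out. Spots with an outlier flag were set to missing, saturated spots were kept, and spots of the same probe (1712 probes were spotted in duplicate) were averaged. The main values were log2 of the processed intensity minus the 75th percentile of the array. A probe was tested when it was well above background on at least 50% of the arrays of at least 1 group compared. Folds against a group with no array well above background used, for each array, the higher of the probe's own signal and the lowest signal among probes well above background.

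Differences were tested with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3 with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05, in 3 comparisons. Testis was set against ovary within the 350 dpf arrays, 250 against 110 dpf within those arrays, and the mean of testis and ovary at 350 dpf against 250 dpf with 3 group means. Slide was tested as a fixed block for the first pair of comparisons. For 350 against 250 dpf, where the slides of the ages differ, it was tested as a random block (duplicateCorrelation, statmod 1.5.0). The sex score used 100 probes per direction with the smallest adjusted p among those at least 2-fold different at 350 dpf, and 100000 resamples of the age labels. It was set against 10000 random pairs of lists matched on mean level in 20 bins. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

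On simulated data with 200 of the probes changed, the share recovered was 42% at 2-fold and 82% at 4-fold for testis against ovary, 38% and 72% for 250 against 110 dpf, and 54% and 84% for 350 against 250 dpf. False calls made up 2.61%, 4.59% and 4.69% of the calls. The simulated noise was independent between probes, whereas at 250 dpf 77.3% of the variance lay along a first component shared across probes. The simulated rates of recovery and false calls therefore do not carry over to these arrays.

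None of the targets (0 of 20978) matched the reference table of gene symbols, and 1 target carries a symbol in its own name. The files do not pair the other IDs with gene names, so the gene lists fixed beforehand and the genes cyp19a1a, foxl2, amh, gsdf and sox9 were not analysed here. Named targets followed a rule: dmrt1c in each comparison, and in each direction the targets with the largest difference among those past the threshold, at least 2-fold different and well above background on every array of the higher group, each represented by its brightest tested probe. The rule allowed 5 named genes per direction; without gene names, 2 targets per direction are given.

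The alternatives were quantile normalization, scaling to the array median, normexp background correction (offset 50), the authors' table, no filter or a stricter filter on dim probes, the slide and the replicate number as blocks, array weights, a trended robust variance, each array left out in turn, and the slide with 3 shorter files left out. For the score they were 50 or 200 probes per direction, quantile normalization, normexp, the authors' table and slide means removed.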

Results

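Gonad RNA of the European sea bass, Dicentrarchus labrax, was measured on 41 single-colour Agilent arrays made for this species, at 3 ages counted in days post fertilization (dpf). The groups were 11 gonads at 110 dpf, 12 gonads at 250 dpf, 9 testes at 350 dpf and 9 ovaries at 350 dpf, with 1 gonad sample per array. The sample labels call the gonads at 110 and 250 dpf undifferentiated. The series text counts 6 testes and 6 ovaries among the 250 dpf samples but does not say which is which, so no array of that age was given a sex. Each array carried 42091 probes of 60 bases for 20978 target sequences, of which 20888 had 2 probes. Only 1 target carried a gene symbol in the files, dmrt1c; all others are reported by the array's own probe and target names.

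Levels below are log2 values of the background-corrected signal relative to the 75th percentile of the same array, so that a level of 0 is the signal at that percentile. That percentile averaged 899.7 ± 211 signal units (SD, n = 11; range 565 to 1228) at 110 dpf and 3084 ± 1519 (n = 12; range 1511 to 5276) at 250 dpf. It averaged 3409.5 ± 1145 (n = 9) in testis and 3502 ± 683 (n = 9) in ovary at 350 dpf. The share of probes well above background averaged 71.3% at 110 dpf, 81.1% at 250 dpf, 84.5% in testis and 77.9% in ovary. The number of arrays limits the precision of every value.

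Testis and ovary at 350 dpf were compared to find the targets that differ between the sexes once the gonads are labelled by sex. They differed at most of the probes, and the largest differences lay on the testis side. At least 16-fold differences comprised 2747 probes higher in testis and 7 higher in ovary, and 172 probes were at least 64-fold higher in testis against 0 in ovary. A set of 865 probes was well above background on all 9 testis arrays and on none of the 9 ovary arrays, while the converse held for 1 probe. Among all probes past the threshold, the median log2 difference was 2.25 for those higher in testis and -1.14 for those lower.

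The dmrt1c target was higher in testis at each of its 3 probes; dmrt1 genes encode transcription factors known for their part in testis development. Its brightest probe, CUST_12_PI428121236 (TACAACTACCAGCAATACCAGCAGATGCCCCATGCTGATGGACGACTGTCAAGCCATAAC), averaged -2.48 ± 1.37 (SD, n = 9) in testis and -5.00 ± 0.41 (n = 9) in ovary. The difference was 2.52 ± 0.45 log2 units (SE; limma adjusted p = 5.98e-05), with 1 testis array, replicate 1, at -5.59, below the ovary mean. After quantile normalization it was 1.46 log2 units (limma adjusted p = 0.0107). The other probes of dmrt1c differed by 3.57 log2 units (CUST_10_PI428121236, limma adjusted p = 4.7e-08) and 3.1 log2 units (CUST_11_PI428121236, limma adjusted p = 4.68e-06). At the latter probe only 5 of the 9 ovary arrays were well above background, so the size of its difference is uncertain.

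Of the targets without a gene name, the largest rises in testis were at CUST_26_PI428121236 and CUST_35336_PI428273605, whose targets the files name only by sequence accessions. CUST_26_PI428121236 (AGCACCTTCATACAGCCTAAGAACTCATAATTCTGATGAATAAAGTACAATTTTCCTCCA) averaged 2.24 ± 1.80 (SD, n = 9) in testis and -7.16 ± 0.38 (n = 9) in ovary, a difference of 9.40 ± 0.57 log2 units (SE; limma adjusted p = 9.26e-11). CUST_35336_PI428273605 (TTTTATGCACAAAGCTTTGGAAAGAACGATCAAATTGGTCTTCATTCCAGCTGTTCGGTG) averaged 3.34 ± 1.08 (n = 9) in testis and -5.93 ± 0.74 (n = 9) in ovary, a difference of 9.27 ± 0.41 log2 units (SE; limma adjusted p = 7.06e-12). On the ovary side, DLPD15948 (probe CUST_24507_PI428273605, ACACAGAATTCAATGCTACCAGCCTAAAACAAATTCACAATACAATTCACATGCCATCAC) averaged -8.05 ± 1.55 in testis, where 4 of the 9 arrays were well above background, and -2.84 ± 0.36 in ovary. Its difference was -5.20 ± 0.50 log2 units (SE, n = 9 per sex; limma adjusted p = 2.73e-08), and its second tested probe lay in the same direction without passing the threshold. The size of that difference was not settled, being -2.49 log2 units after normexp background correction, -2.72 for the mean of both probes and -1.08 in the authors' value table. DLPD18103 (probe CUST_32582_PI428273605, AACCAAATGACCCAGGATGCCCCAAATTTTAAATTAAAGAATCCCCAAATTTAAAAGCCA), with no second probe tested, averaged -5.51 ± 1.39 in testis and -1.02 ± 0.41 in ovary, a difference of -4.48 ± 0.45 log2 units (SE, n = 9 per sex; limma adjusted p = 5.7e-08) that was -1.33 in the authors' value table.

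In the limma test of 36092 probes, 27128 passed an adjusted p of 0.05, 14102 of them higher and 13026 lower in testis. The difference was at least 2-fold for 11483 higher and 7722 lower probes. All 9 testis arrays lay above all 9 ovary arrays at 8419 probes and below them at 6621, where chance gives 0.00411% of probes in either direction. Of 17190 targets with at least 2 tested probes, 6250 had every probe higher, 6032 every probe lower, and 129 had probes past the threshold in opposite directions. With the slide as a block, 24954 probes passed, 13038 higher and 11916 lower. Within the 5 slides, between 93.8% and 99.7% of the 27128 probes kept the sign of the fit, but they were called on these same arrays, which favours agreement. Which sex had more probes depended on the scaling: 52.0% of the calls were higher in testis as scaled here, 41.1% after quantile normalization, 33.5% after scaling to the array median, 44.1% after normexp background correction and 41.1% in the authors' value table. These settings moved the median of all probes from 0.07 to -0.28, -0.68, -0.11 and -0.16 log2 units, but in each of them the at least 16-fold differences were mostly higher in testis (960 against 14, 1128 against 65, 643 against 0, and 114 against 0).

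**Figure D1:**
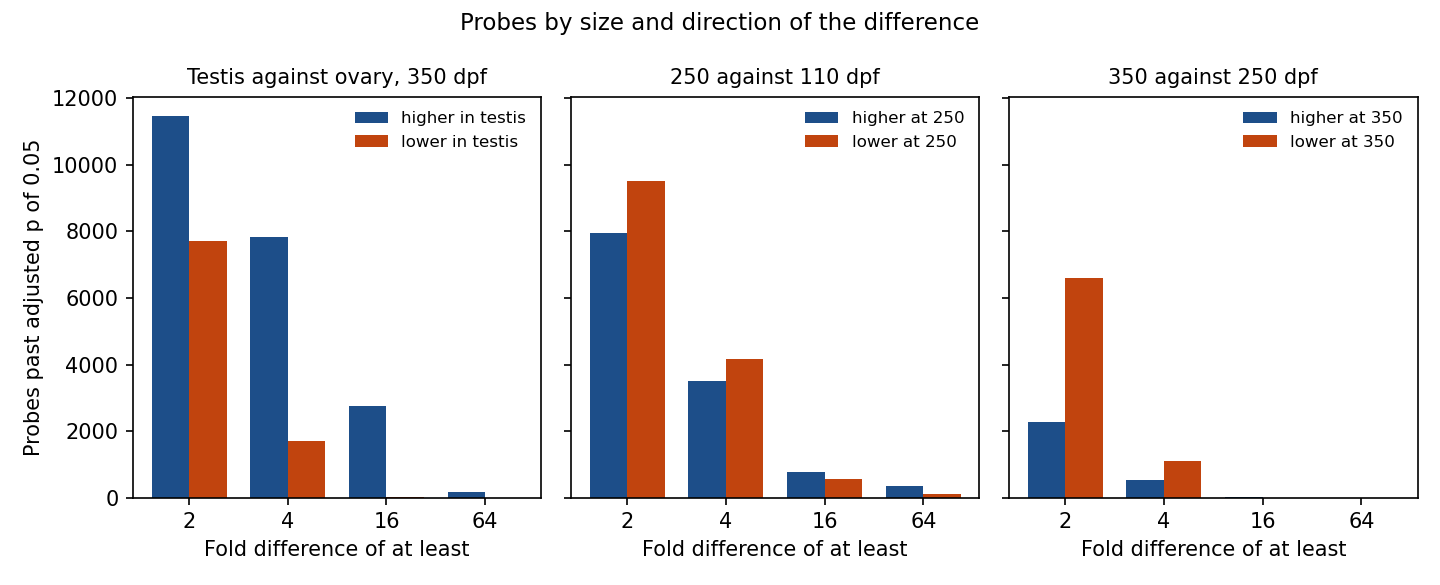
Number of probes past an adjusted p of 0.05 (vertical axis) by the fold difference they reached (horizontal axis: at least 2-, 4-, 16- or 64-fold), with 1 panel per comparison and bars for probes higher and lower in the group named first. In the testis against ovary panel, 2747 probes were at least 16-fold higher and 7 at least 16-fold lower.

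The comparison of 250 with 110 dpf asks how the gonad changes between the youngest age and the age at which the series text counts testes and ovaries. The label protocols count males and females at 110 dpf as well, so both ages are described as of mixed sex. As scaled here, somewhat fewer probes rose than fell, but among the largest changes more rose. At least 64-fold differences comprised 339 probes higher at 250 dpf and 109 lower, and at least 16-fold differences 775 and 571. These counts depended on the scaling: after normexp background correction they were 76 and 51 at 64-fold and 309 and 282 at 16-fold, and in the authors' value table, which holds targets, 27 and 9, and 144 and 45. A set of 275 probes was well above background on all 12 arrays at 250 dpf and on none of the 11 at 110 dpf, against 2 probes for the converse, although arrays at 110 dpf were dimmer.

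The dmrt1c target rose at 2 of its 3 probes. CUST_12_PI428121236 averaged -6.53 ± 0.94 (SD, n = 11) at 110 dpf, where 1 of the 11 arrays was well above background, and -3.05 ± 1.29 (n = 12) at 250 dpf, where all 12 were. The difference was 3.48 ± 0.46 log2 units (SE; limma adjusted p = 9.66e-07), but 0.77 log2 units (limma adjusted p = 0.0444) after normexp background correction, so that its size depended on how the background at 110 dpf was treated. CUST_10_PI428121236 differed by 2.23 log2 units (limma adjusted p = 0.000128) and CUST_11_PI428121236 by 1.31 log2 units (limma adjusted p = 0.102), which did not pass. At both of these, too, 1 of the 11 arrays at 110 dpf was well above background, so the sizes rest on signals that were mostly not told from background. The arrays at 250 dpf spread widely at CUST_11_PI428121236, with a mean of -5.70 ± 2.12 (SD, n = 12) and a range of -8.77 to -3.11. Replicates 2 to 7 lay between -8.77 and -6.86 there and replicates 8 to 13 between -4.61 and -3.11, so the mean rise is not that of a typical array. At CUST_10_PI428121236 these ranges were -6.07 to -4.39 and -3.54 to -2.86, while at CUST_12_PI428121236 they overlapped.

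**Figure D2:**
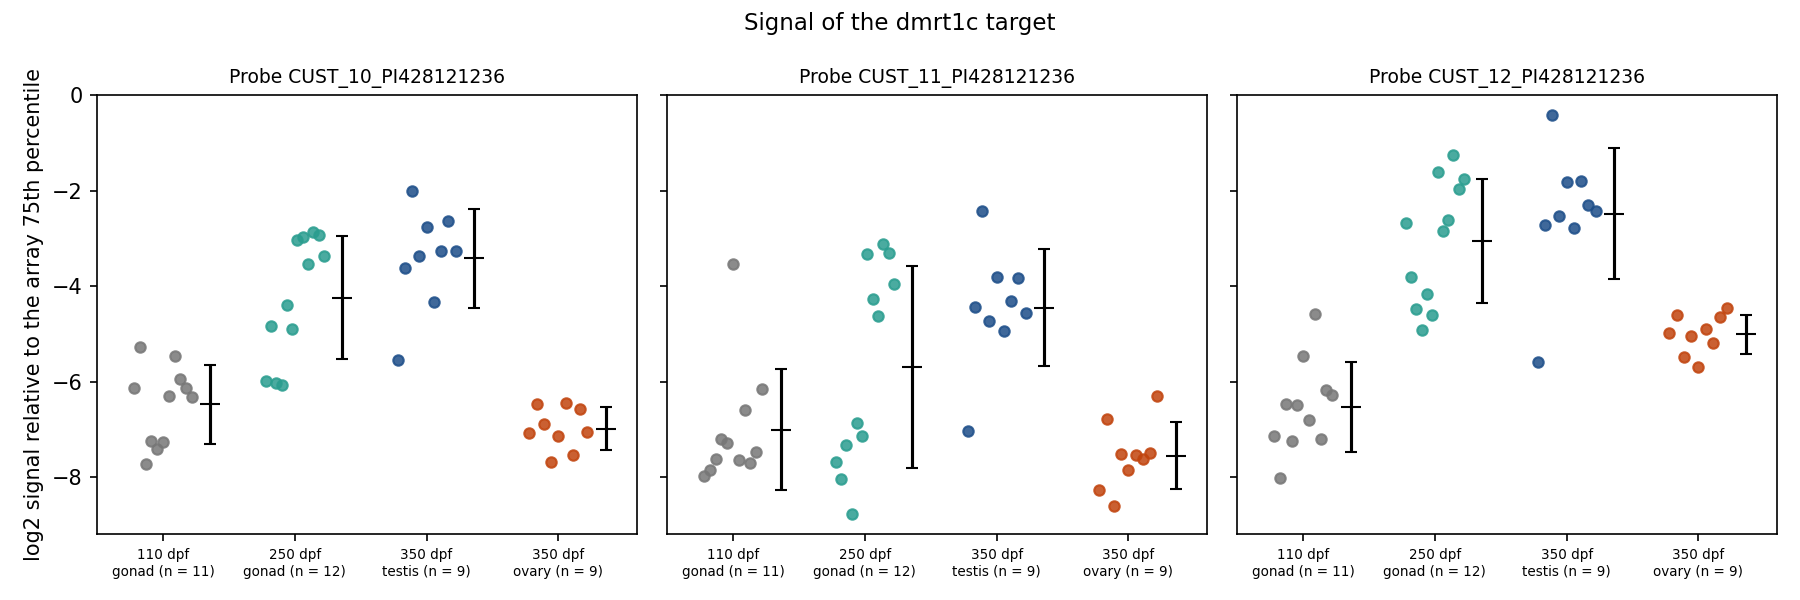
Level of the dmrt1c target (vertical axis: log2 signal relative to the array's 75th percentile) on each array, with 1 panel per probe and the 4 groups along the horizontal axis; points are arrays, and bars give the mean ± SD. In the panel of CUST_12_PI428121236 the group means run from -6.53 at 110 dpf to -3.05 at 250 dpf, -2.48 in testis and -5.00 in ovary at 350 dpf.

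Among the targets with the largest log2 rises as scaled here was ASSEMBLY_C8353 (probe CUST_7472_PI428273605, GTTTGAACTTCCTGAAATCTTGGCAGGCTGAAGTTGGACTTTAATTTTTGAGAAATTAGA), from -5.98 ± 3.72 (SD, n = 11) to 4.13 ± 2.27 (n = 12), a difference of 10.11 ± 1.20 log2 units (SE; limma adjusted p = 2.49e-07). At 110 dpf it was well above background on replicate 9 alone, at 5.02, so that its fold change has only a lower bound and its rank among probes absent at that age was not determined. Without that array the difference was 11.22 ± 0.71 log2 units (limma adjusted p = 1.71e-11), or at least 1033-fold against the lowest signals above background. ASSEMBLY_REP_C15655 (probe CUST_11651_PI428273605, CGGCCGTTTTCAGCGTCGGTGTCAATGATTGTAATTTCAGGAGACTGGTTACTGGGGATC) rose from -6.29 ± 3.47 to 3.72 ± 3.12, by 10.01 ± 1.30 log2 units (SE; limma adjusted p = 8.46e-07). It too was above background at 110 dpf on replicate 9 alone, at 4.09, and without that array rose by 11.05 ± 0.95 log2 units (limma adjusted p = 2.39e-09), or at least 782-fold.

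The largest falls were from levels far above the 75th percentile at 110 dpf to levels far below it at 250 dpf. ASSEMBLY_C8857 (probe CUST_7817_PI428273605, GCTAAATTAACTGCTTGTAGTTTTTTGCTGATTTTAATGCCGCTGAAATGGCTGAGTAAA) went from 6.32 ± 1.92 (SD, n = 11) to -5.47 ± 2.07 (n = 12), a difference of -11.79 ± 0.79 log2 units (SE; limma adjusted p = 2.56e-11), with 9 of the 12 older arrays still well above background. ASSEMBLY_REP_C1038 (probe CUST_1408_PI428273605, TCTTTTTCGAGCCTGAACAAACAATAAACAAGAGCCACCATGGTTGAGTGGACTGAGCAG) went from 5.79 ± 1.32 to -5.36 ± 1.83, a difference of -11.15 ± 0.64 log2 units (SE; limma adjusted p = 1.79e-12). In both pairs of targets the second tested probe passed the threshold in the same direction. In the authors' value table the 4 differences were smaller, at 6.61, 6.52, -7.68 and -7.40 log2 units in the order given, and after normexp correction that of CUST_11651_PI428273605 was 6.57.

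In the limma test of 34962 probes, 23918 passed, 11119 higher and 12799 lower at 250 dpf, and 7956 and 9514 by at least 2-fold. All 12 arrays at 250 dpf lay above all 11 at 110 dpf at 3234 probes and below them at 1873, where chance gives 0.000148% in either direction. Of 16622 targets with at least 2 tested probes, 5126 had every probe higher, 5610 every probe lower, and 68 had probes past the threshold in opposite directions. With the slide as a block 22969 probes passed, 10617 higher and 12352 lower. Within the 6 slides between 98.1% and 99.8% of the 23918 probes kept their sign, but they were called on these same arrays, which favours agreement. The share of calls that were higher was 46.5% as scaled here and 32.3% after normexp background correction, which moved the median of all probes from -0.14 to -0.52 log2 units. Per the labels gonads were isolated in full only at the older ages, so tissue around the gonad cannot be told apart from age in this comparison.

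A sex score asked whether arrays of a single age already differ along the difference that separates testis from ovary at 350 dpf. Males and females are counted at both younger ages, at 110 dpf by the label protocols, but no array of these ages carries a sex label. The score of an array was the mean level of the 100 probes most clearly higher in testis minus that of the 100 probes most clearly higher in ovary, all chosen on the 350 dpf arrays. The 110 dpf arrays had scores close to one another, at 2.77 ± 0.36 (SD, n = 11; range 1.99 to 3.31), whereas the 250 dpf arrays spread from -5.85 to 2.71, with a mean of -0.42 ± 3.21 (SD, n = 12). At 350 dpf the score was 1.41 ± 0.72 (n = 9) in testis and -6.60 ± 0.21 (n = 9) in ovary. The probes higher in testis averaged 0.13 ± 0.31 at 110 dpf and -2.05 ± 2.39 at 250 dpf. The probes higher in ovary averaged -2.63 ± 0.11 and -1.63 ± 0.84, so both sets of probes varied more at 250 dpf.

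The SD at 250 dpf was 8.97 times that at 110 dpf, and the mean absolute deviation from the age median differed between the ages (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Random pairs of probe lists of matched level had a median SD of 0.11 at 110 dpf and 0.13 at 250 dpf, and 0 of 10000 pairs spread as widely as the score at either age. The lists were matched on level alone and not on how alike their probes vary. This comparison therefore does not by itself show a spread along the difference between the sexes. With slide means removed from the scores the ratio of the SDs was 6.79.

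**Figure D3:**
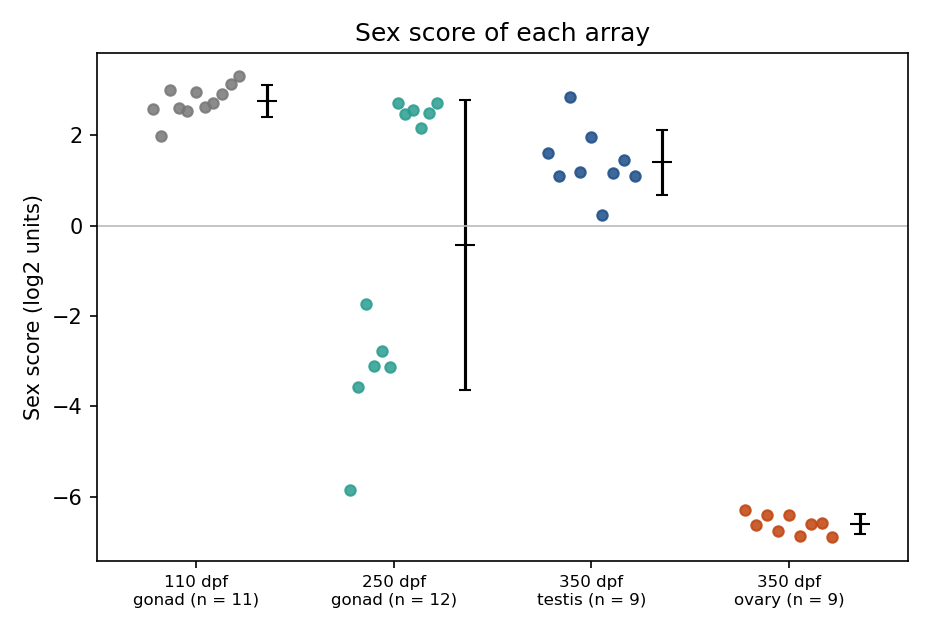
Sex score of each array (vertical axis, log2 units) by group (horizontal axis); points are arrays, and bars give the mean ± SD. The 11 arrays at 110 dpf lie between 1.99 and 3.31 and the 12 arrays at 250 dpf between -5.85 and 2.71, while testis and ovary at 350 dpf do not overlap.

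The mean of testis and ovary at 350 dpf was set against 250 dpf to follow the later change of the gonad. In this mean, in which opposite changes of the sexes cancel, few probes differed by much: 7 were at least 16-fold higher at 350 dpf and 1 at least 16-fold lower. Neither sex was compared with itself, since the 250 dpf arrays carry no sex label and the series text counts testes and ovaries among them. Their mean sex score, -0.42, also lay nearer to testis (1.41) than to ovary (-6.60). The unequal counts below therefore do not show that ovary changed more than testis. Against the same 250 dpf arrays, testis differed at 3802 probes, 1775 higher and 2027 lower (854 and 740 by at least 2-fold), and ovary at 26454 probes, 11513 higher and 14941 lower (6824 and 11965 by at least 2-fold). Both sexes passed in the same direction at 1647 probes, 851 higher and 796 lower, where independent lists of these sizes would share 564.3 and 836.3. With the 250 dpf arrays divided so that each sex had its own reference arrays, 34 or 62 probes were higher in both and 21 or 13 lower. Each of these fits held only part of the 250 dpf arrays and 1 sex, so fewer probes could pass for that reason too. The lower counts therefore mix the loss of arrays with the removal of the shared reference. In 20 simulations of unchanged groups against shared reference arrays no probe passed in both, the highest count being 0. As no difference was simulated in either sex, hardly any probe could pass. The simulations therefore do not show how many of the 1647 probes come from the shared reference arrays.

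The dmrt1c target differed between the sexes at 350 dpf, with the mean level at 250 dpf between them. That mean is not the level of a typical array at CUST_11_PI428121236. There, replicates 2 to 7 at 250 dpf lay between -8.77 and -6.86, and replicates 8 to 13 between -4.61 and -3.11. CUST_10_PI428121236 averaged -4.24 at 250 dpf, -3.42 in testis and -6.98 in ovary; CUST_11_PI428121236 averaged -5.70, -4.45 and -7.55, and CUST_12_PI428121236 -3.05, -2.48 and -5.00. The mean of the sexes, which hides this, did not differ from 250 dpf past the threshold at 2 of the 3 probes: -0.69 log2 units at CUST_12_PI428121236 (limma adjusted p = 0.163) and -0.30 at CUST_11_PI428121236 (limma adjusted p = 0.666). At CUST_10_PI428121236 the mean of the sexes was lower by 0.96 log2 units (limma adjusted p = 0.0358), although the testis mean was above that at 250 dpf.

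The largest rises by 350 dpf were at ASSEMBLY_REP_C11885 (probe CUST_9617_PI428273605, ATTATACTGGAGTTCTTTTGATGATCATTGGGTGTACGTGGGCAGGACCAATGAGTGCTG) and ASSEMBLY_C25120 (probe CUST_15924_PI428273605, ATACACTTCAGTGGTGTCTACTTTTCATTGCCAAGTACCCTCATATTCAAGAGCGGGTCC). The first averaged -2.31 ± 3.61 (SD, n = 12) at 250 dpf, 0.57 ± 2.06 (n = 9) in testis and 2.89 ± 0.60 (n = 9) in ovary, a rise of 4.04 ± 0.92 log2 units (SE; limma adjusted p = 0.0014). The second averaged -4.72 ± 2.50, -2.02 ± 2.06 and 0.60 ± 1.12, a rise of 4.01 ± 0.73 log2 units (SE; limma adjusted p = 0.000178). The largest falls were at ASSEMBLY_C10412 (probe CUST_8779_PI428273605, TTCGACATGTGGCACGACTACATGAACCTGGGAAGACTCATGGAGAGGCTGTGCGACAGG) and DLPD10315 (probe CUST_32856_PI428273605, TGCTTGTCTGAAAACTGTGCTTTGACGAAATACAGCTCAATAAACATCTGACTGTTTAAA). The first averaged -1.55 ± 2.69 (SD, n = 12), -3.06 ± 3.60 in testis and -6.70 ± 0.55 in ovary, a difference of -3.33 ± 0.94 log2 units (SE; limma adjusted p = 0.00625). DLPD10315 averaged -1.89 ± 3.07, -4.71 ± 1.5 in testis and -5.43 ± 1.33 in ovary, a difference of -3.18 ± 0.80 log2 units (SE; limma adjusted p = 0.00291), with 1 testis array, replicate 5, at -1.02. At CUST_9617_PI428273605 and CUST_15924_PI428273605 the authors' value table gave differences of -0.06 and -0.05, and at CUST_32856_PI428273605 one of 1.27, none past the threshold (limma adjusted p = 0.959, 0.948 and 0.137). At CUST_8779_PI428273605 it gave -1.42 (limma adjusted p = 0.139). That table holds little of the difference between the slide sets, and so between these ages, so its values are no separate check of these changes. After normexp correction the differences at CUST_15924_PI428273605 and CUST_8779_PI428273605 were 2.58 and -2.03 log2 units. With the replicate number as a block neither fall passed, at -2.20 log2 units for CUST_8779_PI428273605 (limma adjusted p = 0.1) and -2.07 for CUST_32856_PI428273605 (limma adjusted p = 0.0748). Replicates 11 to 13 at 250 dpf have no 350 dpf array of their number and add nothing under that block.

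In the limma test of 36214 probes, 16767 passed, 6484 higher and 10283 lower at 350 dpf, and 2258 and 6604 by at least 2-fold. The 350 dpf arrays lay on other slides than the 110 and 250 dpf arrays, so slide set and age cannot be told apart. With slide as a random block, which does not separate them either, 21103 probes passed, 8424 higher and 12679 lower. The correlation within slides was negative (-0.185). Each slide with 250 dpf arrays held 1 of replicates 2 to 7 and 1 of replicates 8 to 13, which differed in sex score. The higher count is therefore no added support. Among the targets of the authors' value table, 2348 passed, and after normexp background correction 10717 probes. With the replicate number as a block, although the numbers do not pair the samples, 6615 probes passed, 3064 higher and 3551 lower, and 766 and 1930 by at least 2-fold. Replicates 11 to 13 at 250 dpf, which have high scores, share no number with a 350 dpf array and add nothing to that fit. It thus rests on replicates 2 to 10 at 250 dpf, among which the low scores of replicates 2 to 7 weigh more. The share of calls that were higher was 38.7% as scaled here, 53.6% after quantile normalization and 54.0% after scaling to the array median, so the larger direction was not settled. It was 67.9% in the authors' table. That table holds little of the difference between the slide sets (SD 0.145 against 1.38), and so between these ages. Its count and share are therefore no separate check of this comparison. The median of all probes moved from -0.16 to 0.04 (quantile normalization), 0.06 (array median) and 0.01 log2 units (authors' table).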

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

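The tests of array brightness, slide and normalization for the sex score, of the scaling and of the single 110 dpf array were chosen after the results were seen. At 2 of the named probes a sample, not the same one, stood far from the other testes at 350 dpf. About 1 in 20 groups does so by chance: 34 sets of values were tested and 1.7 expected. The level of dmrt1c at CUST_12_PI428121236 was -5.59 in testis replicate 1 and between -2.78 and -0.41 in the other testes. Replicate 1 was also the lowest testis at the dmrt1c probes CUST_10_PI428121236 (-5.55, next lowest -4.32) and CUST_11_PI428121236 (-7.036, next lowest -4.945). These 2 probes were not among the sets tested, so the expected number does not cover this recurrence. The level of DLPD10315 at CUST_32856_PI428273605 was -1.02 in testis replicate 5 and between -5.83 and -3.94 in the others.

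The sex score spread 8.97 times as widely at 250 dpf as at 110 dpf. Slides held little of this, since 96.2% of the score variance at 250 dpf lay within slides, and the ratio of the SDs stayed at 7.48 or more after quantile normalization, normexp correction or in the authors' table. Brightness was too weak a trend to be the whole cause: the slope of the score on log2 brightness within the other groups (-0.734 ± 0.159 SE, 29 arrays) gave, at its 95% bound, 22.4% of the score range at 250 dpf. Across probes, the first component of variation within 250 dpf held 77.3% of the variance and correlated with the difference between testis and ovary at 350 dpf with an absolute r of 0.891 (probes are not independent), against 0.092 within 110 dpf. Within testis at 350 dpf, which holds a single sex, it was 0.684, so a high r alone does not show that both sexes are present. The label protocols count males and females at 110 dpf, so the low r there does not show a single sex either. The series text counts testes and ovaries at 250 dpf, and the wide spread is consistent with these being already apart in expression at that age, as a hypothesis; a weaker part of brightness in the spread stays open, since the brighter arrays at that age had the lower scores.

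One array at 110 dpf, replicate 9, carried signal that the others of its age lacked. Of 26230 probes well above background on all arrays at 250 and 350 dpf, 320 were so on exactly 1 array at 110 dpf, and 255 of these on replicate 9, against 25 on the next array. Their median level was -2.65 there, -6.99 on the other 110 dpf arrays, -0.28 at 250 dpf, and -0.13 in testis and 1.92 in ovary at 350 dpf. A mislabelled older sample was argued against by the 452 probes at least 16-fold higher at 110 dpf, whose median level there differed from that of the other 110 dpf arrays by -0.73 log2 units, from 1.04 to 0.30, against -4.40 at 250 dpf. RNA carried over from an older sample could not be told apart from a more advanced gonad, since the log2 ratio to the closest older array, which lay on the same slide, had an SD of 0.683 over these probes, above the 0.3 set for a single source and below the 0.939 between arrays of an older group.

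More probes were at least 2-fold higher in testis than in ovary as scaled here (59.8% of such calls), but the excess at this size may come from the scaling. After scaling to the array median the share was 35.98%, and after quantile normalization 45.4%. The excess among at least 16-fold differences was present under all of the scalings run, with 1128 higher against 65 lower after scaling to the array median. No biological explanation was tested for it.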

How the results depend on the processing

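The alternatives were chosen before the data were examined, except the fit with the sex score as a covariate, which was chosen after the results were seen. Arrays left out aside, 140 of the counts and score ratios stayed within 1.5 times their main value or on their side of the threshold, and 41 counts moved further. At the named probes, of which dmrt1c was tried at CUST_12_PI428121236 alone, 77 values kept direction and call, 3 lost significance and 4 reversed, but a call that was kept could differ much in size, as at dmrt1c between 250 and 110 dpf (0.77 log2 units after normexp correction). The score ratio lay between 6.79 (slide means removed) and 11.1 (50 probes per direction), with a permutation p of 1e-05 under each of these alternatives.

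The authors' table gave 13891 calls for testis against ovary (5705 higher, 8186 lower) and 12006 for 250 against 110 dpf (5951 higher, 6055 lower). It holds targets in place of probes, by construction fewer, and the share of those tested that passed was close to that of the probes (74% against 75.16%, and 65.92% against 68.41%). This does not account for the direction in testis against ovary, where 41.07% of the calls were higher against 51.98%, beside a median of -0.16 against 0.07 log2 units over all values; what in that table's processing caused it was not tested. For 350 against 250 dpf it gave 2348 (1595 higher, 753 lower). Little of the difference between the slide sets, and so between these ages, remains in that table (SD 0.145 against 1.38), which also applies to the reversals at CUST_9617_PI428273605 (-0.064), CUST_15924_PI428273605 (-0.05) and CUST_32856_PI428273605 (1.27), and to CUST_8779_PI428273605 (-1.42, adjusted p = 0.139 with limma). Scaling to the array median raised the probes lower in testis to 19592, beside the shift of the median by -0.68 log2 units. Restricting the test to probes well above background on every array left 6907 higher at 250 dpf, by construction, because 110 dpf arrays were dimmer and probes absent there were not tested. For 350 against 250 dpf, normexp gave 10717 (5690 lower), for which the cause was not tested, and requiring both sexes to pass gave 1647 (851 higher, 796 lower), by construction.

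With the replicate number as a replicate block, 25639 probes passed for testis against ovary and 22990 for 250 against 110 dpf, but 6615 for 350 against 250 dpf (3064 higher, 3551 lower), where dmrt1c at CUST_12_PI428121236 gave 0.023 log2 units. Under that block CUST_8779_PI428273605 (-2.20) and CUST_32856_PI428273605 (-2.07) lost their calls, and the calls at the other probes tried did not change. The call of dmrt1c at CUST_10_PI428121236 was not tried under that block. For 350 against 250 dpf the block also leaves replicates 11 to 13 at 250 dpf without weight, since no 350 dpf array has their number. Its results there therefore come from fewer 250 dpf arrays, with a larger part of low sex scores. The numbers do not pair the samples: deviations of same-numbered arrays correlated between -0.099 and 0.122 for testis and ovary (2 of 8 pairs over 0.1), -0.274 and 0.172 for 250 and 110 dpf (3 of 11), and -0.648 and 0.708 for testis and 250 dpf (5 of 8). At most 2 arrays of any pair of groups correlated best with their own number.

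Leaving out each array in turn gave 26542 to 27541 probes for testis against ovary, 22840 to 24656 for 250 against 110 dpf (23697 without replicate 9 at 110 dpf), 13718 to 19279 for 350 against 250 dpf, and a score ratio of 7.96 to 12.2 with a permutation p of 1e-05 to 0.00777. Of 100 splits into groups of these sizes, only the real 1 gave as many probes for testis against ovary (27128, highest other 17317). So it was for 250 against 110 dpf (23918, highest other 22094, with 21.7% of arrays in their real group and absolute r 0.63 with the score). For 350 against 250 dpf, 2 splits gave as many, the real one included (16767, highest other 20920). With 100 splits, these counts alone exclude chance for no comparison. Why other splits gave many calls was not tested. The tests of gene lists and their alternatives, and the score from oocyte and spermatid lists, were not run because the targets have no gene names. Signal over background limits the values at 110 dpf, where 71.3% of the probes were well above it.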

Other observations

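The tests in this part were chosen after the results were seen, including the fit of 250 against 110 dpf with the sex score. The difference between the group means at 250 and 110 dpf ran along that between the sexes, although these comparisons share no array. Of 10788 probes at least 2-fold higher in testis than in ovary at 350 dpf, 6575 were at least 2-fold lower at 250 than at 110 dpf, where 2912.5 would be so if the lists were independent, and 512 were higher. Of 7631 probes at least 2-fold higher in ovary, 4591 were at least 2-fold higher at 250 dpf (1748.1 if independent) and 174 lower. Across 34718 probes the differences correlated with r = -0.597, and probes are not independent replicates. The 250 dpf mean covers unlike arrays, with sex scores of -5.85 to -1.74 on replicates 2 to 7 and 2.16 to 2.71 on replicates 8 to 13. The latter lay within the range at 110 dpf (1.99 to 3.31). These counts thus do not show a shift towards ovary on every array.

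The means of the gonads at 110 and at 250 dpf lay nearer to testis than to ovary at most of the probes that separate the sexes. At 110 dpf, 95.4% of the 11483 probes at least 2-fold higher in testis and 92.1% of the 7722 at least 2-fold higher in ovary had a mean nearer to that of testis. At 250 dpf the shares were 95% and 88.8%, for a mean over arrays that differ widely and not for each array. The lowest values over quantile normalization, scaling to the array median and normexp correction were 87.3% and 82.2% at 110 dpf, and 82.2% and 84.3% at 250 dpf. The probes higher in testis had a median level of -1.70 ± 0.14 (SD, n = 11) at 110 dpf, -3.15 ± 1.27 (n = 12; range -5.27 to -1.68) at 250 dpf, -2.70 ± 0.60 (n = 9) in testis and -5.70 ± 0.15 (n = 9) in ovary, so the lowest of the 250 dpf arrays lay near ovary. The probes higher in ovary had a median level of -2.77 ± 0.22 (SD, n = 11) at 110 dpf, -1.04 ± 1.12 (n = 12; range -2.31 to 0.27) at 250 dpf, -1.09 ± 0.70 (n = 9) in testis and 0.54 ± 0.04 (n = 9) in ovary. These levels set arrays of different slide sets side by side.

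Ovaries at 350 dpf were more alike than testes. The root-mean-square log2 distance of an array from its group mean was 0.467 ± 0.043 (SD, n = 9) in ovary and 0.862 ± 0.199 (n = 9) in testis (exact 2-sided permutation test, p = 4.11e-05, the smallest that 48620 splits can give). The first component within testis held 45.6% of the variance, and its absolute r with the difference between the sexes was 0.684 across probes, against 0.22 within ovary.

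The hypothesis that the difference between 250 and 110 dpf is the difference between the sexes alone was argued against by a fit with the sex score as a covariate. In it 19224 probes passed, 10189 higher and 9035 lower at 250 dpf, and 65.3% of the 23918 calls of the fit without the score were left in the same direction. The covariate itself differs between the ages, so part of what it removed could be a change with age.

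The scores of the 250 dpf arrays fell in separate clusters, with none between -1.74 and 2.16. They are given with the 75th percentile of each array's signal, and no sex was assigned from them. The scores were -5.85 for replicate 2 (percentile 5276), -3.57 for replicate 3 (4451), -1.74 for replicate 4 (4362), -3.09 for replicate 5 (4205), -2.77 for replicate 6 (4739) and -3.12 for replicate 7 (4008). They were 2.71 for replicate 8 (1520.1), 2.48 for replicate 9 (1804), 2.56 for replicate 10 (1747), 2.16 for replicate 11 (1617), 2.50 for replicate 12 (1772) and 2.71 for replicate 13 (1511). The dmrt1c level at CUST_11_PI428121236 lay between -8.77 and -6.86 on replicates 2 to 7 and between -4.61 and -3.11 on replicates 8 to 13. At CUST_10_PI428121236 it lay between -6.07 and -4.39 on the former and between -3.54 and -2.86 on the latter, while at CUST_12_PI428121236 the ranges overlapped (-4.92 to -2.67 and -2.83 to -1.25). A relation of score and brightness at that age was therefore not tested as a correlation. Testis and ovary at 350 dpf had like mean percentiles, at 3409.5 ± 1145 and 3502 ± 683 (SD, n = 9 each), and scores of 1.41 and -6.60.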
